A study of Oryza sativa with 18 samples.

How the data were processed

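RNA sequencing of rice shoot apical meristems was analysed in 18 libraries, 3 in each of 6 groups: GVG:RFT1 and GVG:Hd3a plants with mock solution or dexamethasone, and wild type in long or short days. Per the labels, plants grew at 16 h of light for 8 weeks, the dexamethasone solution held 10 µM with 0.2% Tween, the mock solution held 0.2% Tween, and stranded libraries were read at 50 bp. The authors aligned reads with Bowtie2 to IRGSP-1.0, estimated expected counts per gene with RSEM and used edgeR, with no versions given. The deposited table holds expected counts for 55986 rows in 18 columns. Between 15.1% and 21.1% of a library's values were not whole (tolerance 0.001), and they were rounded for the count models. The 185 rows with no gene name (0.022% to 0.03% of a library's counts) were left out. Total counts ran from 20275883 to 85037386 per library, and the 10 most abundant genes held 3.3% to 6.6% of them. Counting intervals and floors (3 counts for a value of 0) cover counting error only.

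Libraries were grouped by title. For the wild-type comparison the treatment text and the titles conflict for S15 and S19, so fits without both and with both exchanged were planned as alternatives. No 2 libraries were duplicates.

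Each comparison was tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr (minimum count 10, minimum total 15), TMM scaling and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are log2, and their SE is the absolute fold change divided by the square root of the F statistic. Where a group held only a few reads, this SE can be smaller than the counting error alone. CPM (counts scaled to a library total of 1e+06, without the TMM factors) are means with SD over libraries. The biological coefficient of variation was 0.203 for RFT1, 0.265 for Hd3a, 0.167 for wild type by title and 0.0776 over the 4 wild-type libraries with matching labels. The difference between the RFT1 and Hd3a responses was an interaction term over 12 libraries. Genes called in several comparisons were counted against the product of shares and, by pairs, with a one-sided Fisher exact test. The 2 induced genes were compared with an exact permutation test.

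Replicate numbers were taken to pair libraries when residual log expression of every same-numbered pair correlated across genes above 0.1. This held for Hd3a (0.63, 0.40 and 0.52, although DEX replicate 3 and mock replicate 2 also gave 0.51) and failed for RFT1 (-0.21, 0.00 and 0.08) and wild type (0.27, 0.40 and -0.35). Residuals within a group cancel out, so the correlations of its pairs are not independent of each other. The blocked fit was run for all 3 comparisons.

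The 18 gene lists (157 genes) were fixed before the data were examined: florigen, inflorescence MADS, floral organ MADS, SVP-type MADS, TERMINAL FLOWER 1-like, bZIP partners of florigen, KNOX and BELL, panicle branching, SPL and plastochron, gibberellin, cytokinin, auxin transport, YABBY leaf polarity, photosynthesis (leaf markers), secondary wall and vascular, cell cycle, defence and jasmonate, and clock and photoperiod genes. Lists with at least 3 tested members (16) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over lists. An estimated correlation and fry were run beside it. Names were joined to LOC_Os identifiers by hand, since the reference annotation does not hold these identifiers. All 157 were in the table. For 108 the reference held the symbol on the same chromosome and in the same order, 44 symbols were not in it, and 5 (RCN1, OsIDS1, ASP1, FC1 and SPL18) are used there for a gene on another chromosome and were kept as listed. No coordinates are given for this reason. Keeping these 5 departs from a rule set with the lists, to leave out members that the reference names as another gene.

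Genes named in the text follow a rule also fixed before the data were examined: both florigen genes; for each list, up to 4 members with the smallest p; among genes past the threshold with non-overlapping groups and mean CPM of at least 5, those with the largest and smallest fold change, with at most 2 unnamed identifiers per direction; up to 10 genes per direction called in all comparisons; and for the interaction the 5 genes per direction with the smallest p. The 4 unnamed identifiers printed were chosen from those called in all comparisons after their values were seen, as were a few further list members that serve as examples (CAB1R, CAB2R and RCN3).

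Alternatives were DESeq2 1.42.0 size factors, library totals, no filter, mean CPM of at least 1, an absolute log2 fold change of at least 1 for genes called in all comparisons, the DESeq2 Wald test, the replicate block, a joint fit of all 18 libraries and leaving out each library in turn. Added after the data were seen were Hd3a without both libraries numbered 1, genes called in all comparisons with the block and the 4 wild-type libraries, genes called in RFT1 as a list elsewhere, RFT1 against short days over 10 libraries, and the read ratios of RFT1 and Hd3a with each library left out. The tests were tried on simulated changes: 200 genes were changed by 2-fold or 4-fold in negative binomial counts with the means, depths and dispersions of the same libraries. For RFT1 edgeR recovered 65% of 2-fold and 96% of 4-fold changes with 8% false calls, for Hd3a 46% and 81% with 5.2% (block 37% and 77% with 8.8%), and for the 4 wild-type libraries 95% and 100% with 9.7%. DESeq2 gave 24.2% false calls for RFT1 and 30.1% for Hd3a. For the difference between RFT1 and Hd3a edgeR recovered 42% and 83% with 3.1% false calls. The changed genes were drawn from those with higher counts, and genes were simulated independently, with no outlying library or pair effect. The rates for Hd3a and for its block therefore need not hold for the real libraries. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.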

Results

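Gene expression was measured by RNA sequencing in shoot apical meristems of rice (cultivar Nipponbare), the tissue that turns from making leaves to making a panicle when the plant is induced to flower. The 18 libraries fell into 6 groups of 3. Plants carrying GVG:RFT1 or GVG:Hd3a, transgenes built so that dexamethasone switches on the florigen gene RFT1 or Hd3a, were treated with 10 µM dexamethasone (DEX) or a mock solution and labelled 2 days (RFT1) or 5 days (Hd3a). Wild-type plants were kept in long days of 16 h of light or moved to short days of 10 h, the photoperiod that induces rice to flower. All 6 wild-type libraries, the long-day ones included, carry the time label 12SD, and the labels do not say what it means for the long-day plants. The total count per library was 28980812 to 39883610 in RFT1 mock, 40942394 to 55072353 in RFT1 DEX, 25609246 to 42141700 in Hd3a mock, 32995949 to 85037386 in Hd3a DEX, 20275883 to 26439845 in long days and 23620355 to 30546303 in short days. The comparisons ask which genes answer to either florigen and to day length, and which answer to all of them. No group received dexamethasone without a florigen transgene, so effects of the florigen cannot be separated from those of dexamethasone itself. The labels do not say whether replicates were separate pools of plants, so each p-value of a comparison of groups below measures only the spread between these libraries.

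For 2 wild-type libraries the labels conflict. The library S15 is titled long day, replicate 2, and S19 is titled short day, replicate 1, while the treatment text counts sample 15 among the short-day samples and does not list sample 19. The other 4 wild-type libraries carry labels that match (2 per day length), so wild-type values are given for those 4, with S15 and S19 beside them, and for the grouping by title.

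Reads from the induced genes were few. RFT1 (LOC_Os06g06300) had 6, 4 and 38 reads in the RFT1 DEX libraries and 2, 1 and 0 in the RFT1 mock libraries, a depth-scaled ratio of 12.6 with a 95% counting interval of 4.07 to 63.4. DEX replicate 3 held 38 of the 48 reads, and without it the ratio was 3.76 with an interval of 0.968 to 21.3, which includes 1; without mock replicate 1 it was 27.7 and without mock replicate 3 it was 7.98. Hd3a (LOC_Os06g06320) had 2, 4 and 2 reads in Hd3a DEX and 0, 0 and 1 in Hd3a mock, a ratio of 4.8 with an interval of 0.644 to 213, so a difference was not detectable for Hd3a at this depth. An exact two-sided permutation test gave p = 0.1 for each, the smallest p that 3 libraries against 3 allow. Neither gene had a read in any wild-type library. The counts cannot separate transgene from endogenous transcripts, and RFT1 and Hd3a are neighbouring paralogs, so 50 bp reads may be shared between them. Hd3a DEX and Hd3a mock each held 0 RFT1 reads, RFT1 DEX held 0 Hd3a reads and RFT1 mock 1. These counts are too low to settle the point.

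After RFT1 induction for 2 days, 4 of 7 listed MADS-box genes of the inflorescence meristem rose. OsMADS14 (LOC_Os03g54160), a relative of APETALA1 and FRUITFULL, rose from 0.926 ± 0.194 to 82.4 ± 3.78 CPM (counts scaled to a library total of 1e+06; mean ± SD, n = 3 per group), a log2 fold change of 6.48 ± 0.15 (SE). OsMADS15 (LOC_Os07g01820), of the same clade, rose from 0.0786 ± 0.0455 to 48.2 ± 4.18 CPM, OsMADS18 (LOC_Os07g41370) from 34.3 ± 2.88 to 157 ± 5.20 CPM, and OsMADS34 (LOC_Os03g54170), a SEPALLATA-like gene, from 0.0419 ± 0.0521 to 4.53 ± 0.606 CPM. PINE1 (LOC_Os12g42250), a zinc-finger repressor of stem elongation, fell from 110 ± 20.5 to 28.4 ± 2.89 CPM, a log2 fold change of -1.94 ± 0.16.

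Of the 7 genes of the inflorescence MADS list, 4 rose and 0 fell over all genes tested (adjusted p from 1.62e-06 for OsMADS14 and OsMADS15 to 0.00217 for OsMADS34), and 5 were higher and 2 lower when adjusted over the list alone. The 2 lower members, OsMADS50 (-1.31 log2, adjusted p = 0.0606) and OsMADS20 (-0.91, adjusted p = 0.0931), did not pass over all genes. As a set the list was higher than other genes (camera adjusted p = 2.83e-05; adjusted p = 0.127 with an estimated correlation). Of the 4 TERMINAL FLOWER 1-like genes, which antagonise florigen, 3 rose and 3 were higher when adjusted over the list alone. RCN1 (LOC_Os11g05470) rose by 2.44 ± 0.20 (log2, SE), from 13.7 to 74.8 CPM, RCN2 by 4.41 ± 0.51 and RCN4 by 4.5 ± 0.54, while RCN3 gave -0.19 (adjusted p = 0.774). Reads of RCN1 and RCN3, near-identical paralogs, cannot be assigned with certainty. The set test gave adjusted p = 0.000375 for this list, and adjusted p = 0.396 with an estimated correlation.

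Among 12 tested gibberellin genes 1 rose and 2 fell, while 2 were higher and 3 lower when adjusted over the list alone. KS1, an early step of gibberellin synthesis, rose by 1.34 ± 0.17 (adjusted p = 0.0136), and GA2ox1, which inactivates gibberellin, fell by 2.19 log2 units (adjusted p = 0.0284) alongside PINE1. The set test did not pass for gibberellin (adjusted p = 0.516). Of 12 clock and photoperiod genes, LUX rose (2.97 ± 0.48, adjusted p = 0.0346) from 0.082 to 0.666 CPM and PRR73 fell by 1.13 (adjusted p = 0.0328), with 1 higher and 6 lower when adjusted over the list alone. The clock list was lower as a set (adjusted p = 0.0282; adjusted p = 0.396 with an estimated correlation). Photosynthesis genes, the markers of leaf tissue, were also lower as a set (median log2 fold change -0.72, adjusted p = 0.0235; adjusted p = 0.856 with an estimated correlation), although 0 of the 8 passed in edgeR, over all genes or over the list alone. The photosynthesis set did not pass without DEX replicate 1 (adjusted p = 0.364), DEX replicate 3 (0.0868), mock replicate 1 (0.103) or mock replicate 3 (0.0616), nor the clock set without DEX replicate 2 (0.069), DEX replicate 3 (0.0523) or mock replicate 3 (0.0588). No tested member passed over all genes in the lists of KNOX and BELL genes, YABBY leaf polarity genes, floral organ MADS genes, SVP-type MADS genes, bZIP partners of florigen, panicle branching genes, SPL and plastochron genes, cytokinin genes, auxin transport genes, cell cycle genes or secondary wall genes. Median, mean and set direction differed in sign for the cytokinin, floral organ, YABBY, panicle branching and SVP lists, each with an adjusted p for the set of 0.516 or more. Of the lists for florigen and for defence and jasmonate, fewer than 3 members could be tested. The defence gene PBZ1 gave 4.23 ± 1.62 (adjusted p = 0.249) at 5.09 ± 8.23 CPM.

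In all, 264 of 23032 genes passed at an adjusted p of 0.05 in edgeR, 188 higher and 76 lower. DESeq2 called 1274, among them all 264 with the same sign, no filter on low counts gave 506, and a replicate block gave 132 (121 shared). The count was 168 without mock replicate 1, 152 without mock replicate 2 (66 higher and 86 lower, the only one of these fits with more lower than higher), 112 without mock replicate 3, 138 without DEX replicate 1, 59 without DEX replicate 2 and 87 without DEX replicate 3. GA2ox1 lost its call without 4 of the 6 libraries in turn (adjusted p 0.0568 to 0.145), PRR73 without 5 (0.0605 to 0.132) and with a block (0.0519), LUX without each of the 6 (0.0663 to 0.127) and with a block (0.0971), RCN2 without DEX replicate 2 (0.0504), and RCN4 without DEX replicate 2 (0.0662) or 3 (0.0557). OsMADS34 gave 8.02 without mock replicate 3. A joint fit of all 18 libraries, with S15 and S19 by title, called 255 genes in RFT1. In it OsMADS14, OsMADS15, OsMADS34, PINE1, GA2ox1 and PRR73 had adjusted p = 0.0692, 0.0866, 0.128, 0.176, 0.14 and 0.183. None of these 6 passed there, at log2 fold changes of 6.5, 9.15, 6.55, -1.92, -2.16 and -1.11. By title, OsMADS14 ran from 0.719 to 84.3 CPM over the long-day libraries and PINE1 from 25 to 192 over the short-day ones. Whether this spread ended the calls was not tested.

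**Figure D1:**
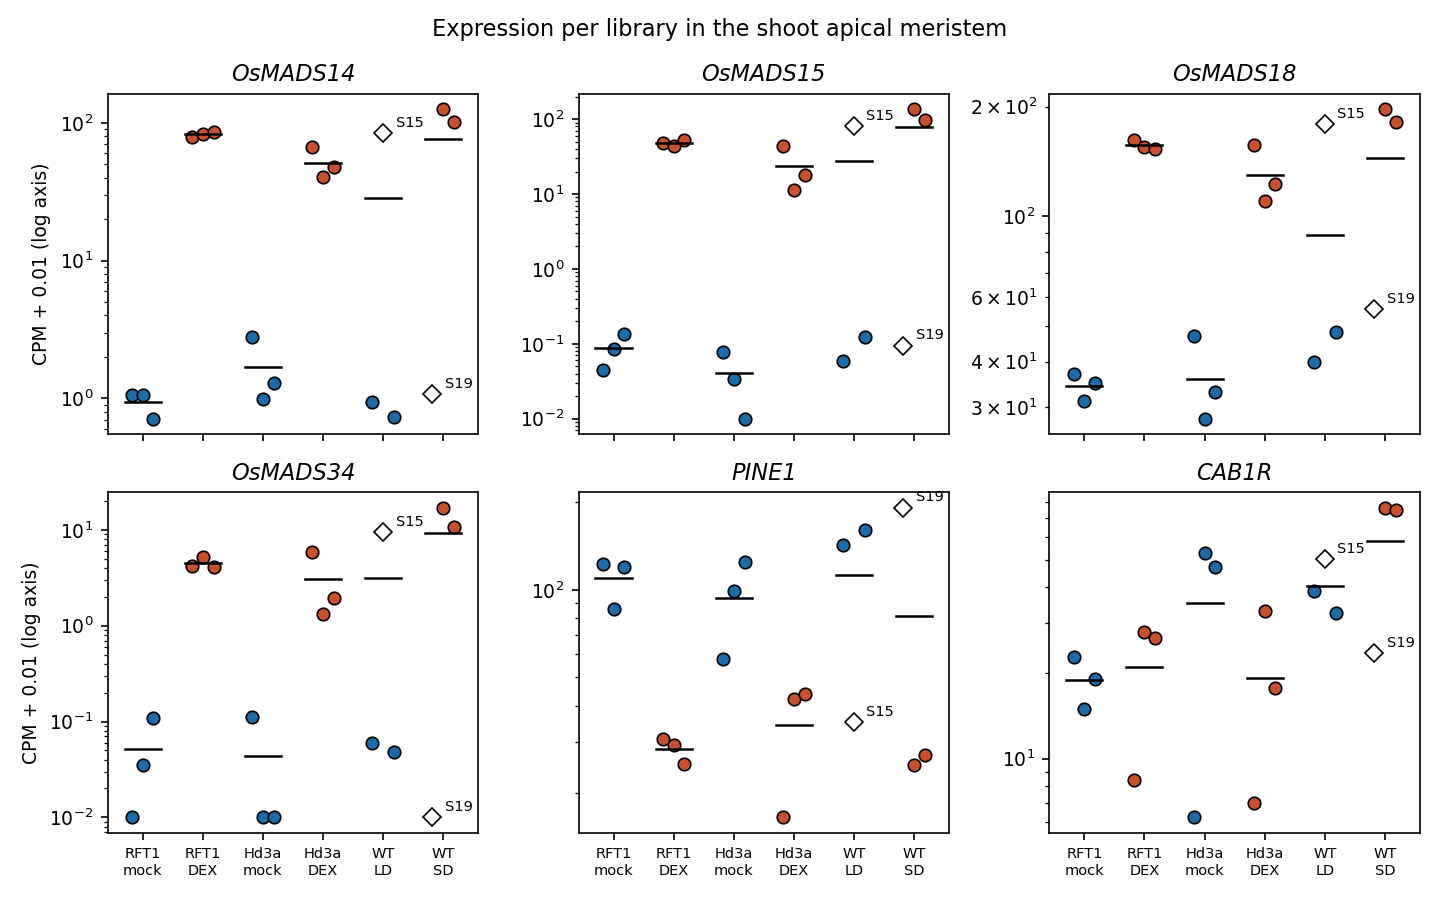
CPM (log axis, 0.01 added) of 5 flowering or stem genes and the leaf marker CAB1R in each of the 18 libraries. Blue points are mock or long-day libraries, red points are DEX or short-day libraries, bars are means of the groups by title, and white diamonds mark S15 and S19, in which OsMADS14 stood at 84.3 and 1.06 CPM.

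In Hd3a induction for 5 days the same MADS-box genes were higher in all 3 DEX libraries than in any mock library, but replicates varied widely and the number of genes called depended on whether equal replicate numbers were treated as pairs. OsMADS14 stood at 51.3 ± 13.4 CPM in DEX and 1.68 ± 0.956 in mock (SD, n = 3 per group), OsMADS15 at 24.1 ± 16.9 and 0.0307 ± 0.0346, OsMADS18 at 130 ± 24.5 and 36.0 ± 9.84, and PINE1 at 34.3 ± 15.4 and 93.7 ± 33.7. In the unpaired edgeR test 0 of 22678 genes passed (lowest adjusted p = 0.107, 1464 genes with an unadjusted p under 0.05), while DESeq2 called 171. Residuals of libraries with the same number correlated across genes (0.63, 0.40 and 0.52), above the 0.1 set for pairing. These correlations are not independent of each other, and DEX replicate 3 and mock replicate 2 also gave 0.51. The pairing of numbers 2 and 3 is therefore not settled. With the replicate number as a block edgeR called 54 genes, 36 higher and 18 lower, 38 of them also in DESeq2.

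With the block, 4 of the 7 inflorescence MADS genes rose. OsMADS14 rose by 5.00 ± 0.17 (log2, SE; adjusted p = 0.00117), OsMADS15 by 9.40 ± 0.27 (0.00112), OsMADS18 by 1.87 ± 0.07 (0.0018) and OsMADS34 by 6.49 ± 0.55 (0.0287). The 3 mock reads of OsMADS34 all lay in mock replicate 1, so that without it the gene was at least 60.2-fold higher (floor of 3 counts over the group), and in the unpaired test its log2 fold change was 5.76 without mock replicate 2 and 5.52 without DEX replicate 1, against 6.47 with all libraries. For OsMADS15 it was 9.48 with all libraries, 10.44 without mock replicate 1 and 8.71 without DEX replicate 1. Mock libraries held 3 reads in all for OsMADS15 and for OsMADS34, against 3426 and 431 in DEX. The depth-scaled ratios were 685 (95% counting interval 234 to 3320) and 86.2 (29.3 to 420). These intervals are wider than the SE of both genes imply. Over the list alone 4 were higher and 2 lower, and the set test gave adjusted p = 0.00642 (adjusted p = 0.385 with an estimated correlation). PINE1 fell by 1.51 log2 units (adjusted p = 0.0185) and was the only one of 12 gibberellin genes to pass, though 5 were higher when adjusted over the list alone, and that list was higher as a set (adjusted p = 0.00687; adjusted p = 0.385 with an estimated correlation). Of 7 KNOX and BELL genes, which maintain the meristem, all had positive fold changes. OSH6 rose by 0.87 ± 0.08 (adjusted p = 0.0314), OSH15 gave 0.73 (0.0985) and OSH1 0.68 (0.134), and 5 were higher when adjusted over the list alone. The KNOX and BELL set was higher (adjusted p = 2.55e-06; adjusted p = 0.385 with an estimated correlation). SPL13 (LOC_Os07g32170), a member of the SQUAMOSA-promoter-binding family, rose by 0.71 ± 0.06 (adjusted p = 0.031), the only one of 14 SPL and plastochron genes to pass, and the set gave adjusted p = 0.0233 (adjusted p = 0.385 with an estimated correlation).

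For the leaf markers, with the block, 0 of 8 photosynthesis genes passed over all genes in edgeR (CAB2R -1.71, adjusted p = 0.156; psaD -0.56, adjusted p = 0.0815), 5 were lower when adjusted over the list alone, and the set was lower (median -1.07, adjusted p = 1.78e-06; adjusted p = 0.385 with an estimated correlation). Secondary wall genes were lower as a set (median -0.49, adjusted p = 0.0233; adjusted p = 0.385 with an estimated correlation) and bZIP partners of florigen higher (median 0.56, adjusted p = 0.00716; adjusted p = 0.385 with an estimated correlation), with 0 members called in either, while 3 bZIP members, OsFD2 and OsFD1 among them, were higher and 2 secondary wall members lower when adjusted over the list alone. TERMINAL FLOWER 1-like genes did not pass over all genes (RCN1 0.93, adjusted p = 0.071; RCN4 2.81, adjusted p = 0.181), and 3 were higher and 1 lower when adjusted over the list alone (set adjusted p = 0.0531). The cell cycle gene CYCB2;1 gave -0.61 (adjusted p = 0.071). No member passed in the clock, cytokinin, auxin, YABBY, floral organ, SVP or panicle branching lists, and the auxin list had a median above 0 and a mean below it. Without the block, 6 sets passed (KNOX and BELL 0.0018; bZIP, gibberellin and, downward, cell cycle 0.0214 each; inflorescence MADS and TERMINAL FLOWER 1-like 0.0491 each), and none with an estimated correlation (lowest adjusted p = 0.475). None of the 6 passed without mock replicate 2 (0.0615 to 0.09), and each of the other libraries ended at least 1 of these calls when left out (0.0508 to 0.259).

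The libraries numbered 1 of both Hd3a groups stood apart from the rest on the second principal component. Without both of them edgeR called 121 genes (66 higher, 55 lower; 35 shared with the blocked fit), and without mock replicate 1 alone it called 5.

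Between the 4 wild-type libraries with matching labels, short days were accompanied by large changes in flowering genes. OsMADS14 rose from 0.828 ± 0.154 to 114 ± 16.7 CPM (SD, n = 2 per group), a log2 fold change of 7.14 ± 0.18 (SE), and OsMADS15 from 0.0814 ± 0.0454 to 117 ± 28.3 CPM. PINE1 fell from 152 to 26.0 CPM, a log2 fold change of -2.53 ± 0.08, and CKX2, a cytokinin oxidase that limits panicle size, from 12.9 to 1.85 CPM (-2.79 ± 0.16). In S15, titled long day, OsMADS14 stood at 84.3, OsMADS15 at 81.6, PINE1 at 35.0 and CKX2 at 1.92 CPM. In S19, titled short day, they stood at 1.06, 0.0847, 192 and 11 CPM.

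All 7 inflorescence MADS genes passed in this fit: OsMADS14, OsMADS15, OsMADS18 (2.12 ± 0.09), OsMADS34 (8.22 ± 0.48) and OsMADS56 (0.82 ± 0.10) rose, and OsMADS50 (-1.27 ± 0.06) and OsMADS20 (-5.21 ± 0.33) fell. OsMADS34 had 811 reads in short days and 2 in long days. Its depth-scaled ratio was 331 (95% counting interval 91.4 to 2740), an interval wider than its SE implies. Adjusted over the list alone the same numbers, 5 and 2, held, and the set test did not pass (adjusted p = 0.0591). RCN1 (1.72 ± 0.11) and RCN4 (1.65 ± 0.36) rose among the 4 TERMINAL FLOWER 1-like genes (set adjusted p = 0.0128; adjusted p = 0.486 with an estimated correlation), and 3 were higher when adjusted over the list alone. Among 12 gibberellin genes KS1 and KAO rose and PINE1, GA2ox1 (-1.62 ± 0.12) and GID1 fell. Among 15 cytokinin genes LOG (1.11 ± 0.18), which makes active cytokinin, and RR2 rose, and CKX2 fell. SPL13 (0.93 ± 0.05), SPL7 and PLA1 rose and SPL3 fell among 14 SPL and plastochron genes. Of 13 panicle branching genes NL1 (1.77 ± 0.16) and RFL (1.07 ± 0.09), the rice LEAFY, rose, and TAW1 (-0.76 ± 0.05) and APO1 (-1.76 ± 0.39) fell. The evening clock gene GI fell from 111 to 56.8 CPM, with PRR73 and ELF3-2 also lower among 11 clock genes.

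The leaf-related lists were higher in short days: all 8 photosynthesis genes rose (median 1.46, set adjusted p = 1.82e-07; adjusted p = 0.44 with an estimated correlation), CAB1R from 35.6 to 75.5 CPM, and 4 of 7 YABBY genes rose (YAB5 by 0.86 and YAB4 by 0.74; set adjusted p = 0.000604; adjusted p = 0.442 with an estimated correlation), 5 when adjusted over the list alone. With S15 and S19 grouped by the treatment text, 3 YABBY genes rose and the set did not pass (adjusted p = 0.0547), and 5 of the 8 photosynthesis genes rose (set adjusted p = 0.000436; adjusted p = 0.511 with an estimated correlation). Among the remaining lists, PIN1c and PIN1d, near-identical paralogs whose reads cannot be assigned with certainty, rose of 5 auxin genes, PCNA and 2 mitotic cyclins of 7 cell cycle genes, OsMADS32 of 4 floral organ genes (OsMADS16 fell), OsMADS22 of 3 SVP-type genes (OsMADS47 and OsMADS55 fell) and a PAL gene of 7 secondary wall genes, while OsFD1 fell of 4 bZIP genes and OSH71 of 7 KNOX and BELL genes. None of these 7 sets passed in this fit, while auxin transport did with wild type grouped by the treatment text (adjusted p = 0.042; adjusted p = 0.428 with an estimated correlation). OsMADS16 (adjusted p = 0.209) and OsMADS47 (0.203) did not pass with that grouping. For the SVP-type list the median (-0.22) and the mean (0.01) differed in sign.

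This fit called 4513 of 23057 genes, 2263 higher and 2250 lower. Grouped by title, 3 libraries against 3, edgeR called 0 of 22788 genes (lowest adjusted p = 0.321, 814 with an unadjusted p under 0.05; DESeq2 7; replicate block 0). There OsMADS14 gave 1.41 ± 1.73 (adjusted p = 0.983) and PINE1 -0.49 ± 0.87. Of the sets, YABBY (adjusted p = 1.25e-05; 0.244 as the adjusted p with an estimated correlation), photosynthesis (0.000387; 0.702) and, downward, KNOX and BELL (0.00449; 0.702) passed by title, the last not without S15 (0.278) or S19 (0.16). Grouped by the treatment text, S15 with short days and S19 with long days, edgeR called 6011 genes, 3952 of them among the 4513 and with the same sign.

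**Figure D2:**
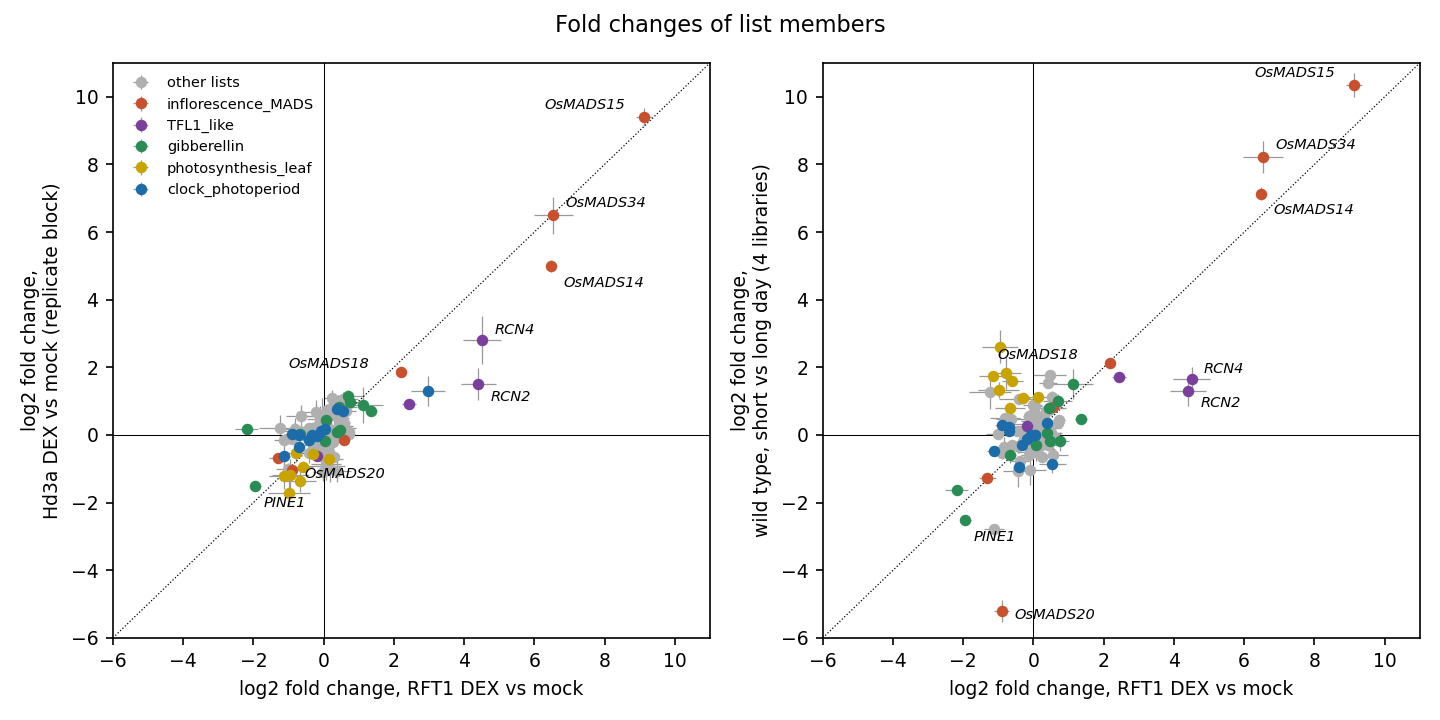
Log2 fold change ± SE of members of the fixed gene lists in RFT1 DEX against mock (horizontal axis) and, on the vertical axes, in Hd3a DEX against mock with the replicate block (127 genes) and in wild type, short against long days over the 4 libraries with matching labels (126 genes). Colours mark lists and the dotted line marks equal values; OsMADS15 lay at 9.13, 9.40 and 10.35.

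A test of the difference between the RFT1 and Hd3a responses over 12 libraries called 0 of 23926 genes in edgeR (1862 with an unadjusted p under 0.05; DESeq2 81). OsMADS14 differed by 1.53 (log2, adjusted p = 0.56), RCN1 by 1.53 (0.37), RCN2 by 2.65 (0.589) and KS1 by 0.62 (0.589). With the replicate block 1 gene passed, LOC_Os12g36680, higher by 2.86 ± 0.19 in the RFT1 response (adjusted p = 0.0117). The check for pairing by replicate number had failed for the RFT1 libraries. Transgene and day of sampling differ together between these groups.

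Grouped by title and unpaired, no gene was called in all 3 comparisons (0 of 21522; DESeq2 0), since edgeR called 0 genes in Hd3a and in wild type. With the block for Hd3a and the 4 wild-type libraries, a combination chosen after the data were seen, 23 of 21579 genes were called in all 3 with the same sign, 20 higher and 3 lower, against 0.0256 and 0.00594 expected from the product of shares. That product takes genes as independent, which they are not. OsMADS14, OsMADS15, OsMADS18 and OsMADS34 were among the 20 higher genes. So were LOC_Os04g29310 (6.31 ± 0.23, 5.48 ± 0.26 and 6.42 ± 0.28 in RFT1, Hd3a and wild type) and LOC_Os12g36680 (5.33 ± 0.17, 2.47 ± 0.14 and 3.18 ± 0.16). PINE1, LOC_Os01g04750 (-1.67 ± 0.18, -1.59 ± 0.18 and -3.77 ± 0.23) and LOC_Os06g36680 (-1.84 ± 0.23, -1.03 ± 0.11 and -1.89 ± 0.13) were the 3 lower genes. With wild type grouped by the treatment text the number was 22.

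By pairs, 22 genes rose and 3 fell in both the RFT1 and the blocked Hd3a fit (0.249 and 0.0615 expected, one-sided Fisher exact p = 2.24e-39 and 3.01e-05). Both inductions share dexamethasone, so this overlap cannot be assigned to florigen alone. The expected numbers and Fisher tests here take genes as independent, which they are not, and do not measure the spread between libraries. In RFT1 and the 4 wild-type libraries 84 rose and 54 fell (16.2 and 7.49 expected, Fisher exact p = 1.82e-41 and 1.3e-37), and 8 rose in RFT1 and fell in short days (15.9 expected). In the blocked Hd3a fit and wild type 26 rose and 4 fell (3.68 and 1.7 expected, Fisher exact p = 1.42e-18 and 0.0825). Of the 188 genes that rose in RFT1, 154 passed the filter on low counts in Hd3a. Genes that stayed low in all Hd3a libraries therefore do not enter the shares that follow. Of the 154, 88.3% had a positive fold change in Hd3a without the block, against 48.9% of all genes. When adjusted over that list, which was chosen on other libraries, 40 passed (set p = 1.76e-30; p = 0.00474 with an estimated correlation). Of the 76 genes that fell in RFT1, 71.1% had a negative fold change in Hd3a, against 51.1% of all genes, and 6 passed over that list (set p = 2.46e-08; p = 0.251 with an estimated correlation). Across genes, which are not independent replicates, log2 fold changes of RFT1 and Hd3a had a Pearson correlation of 0.42 (Spearman 0.24, 22248 genes). For RFT1 and wild type it was 0.10 by title (Spearman 0.04) and 0.32 over the 4 libraries (Spearman 0.24), and for Hd3a and wild type -0.06 (Spearman -0.15) and 0.05 (Spearman -0.15). Without the library S15 the RFT1 and wild type value was 0.26, and without wild-type long day replicate 3 it was -0.07.

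**Figure D3:**
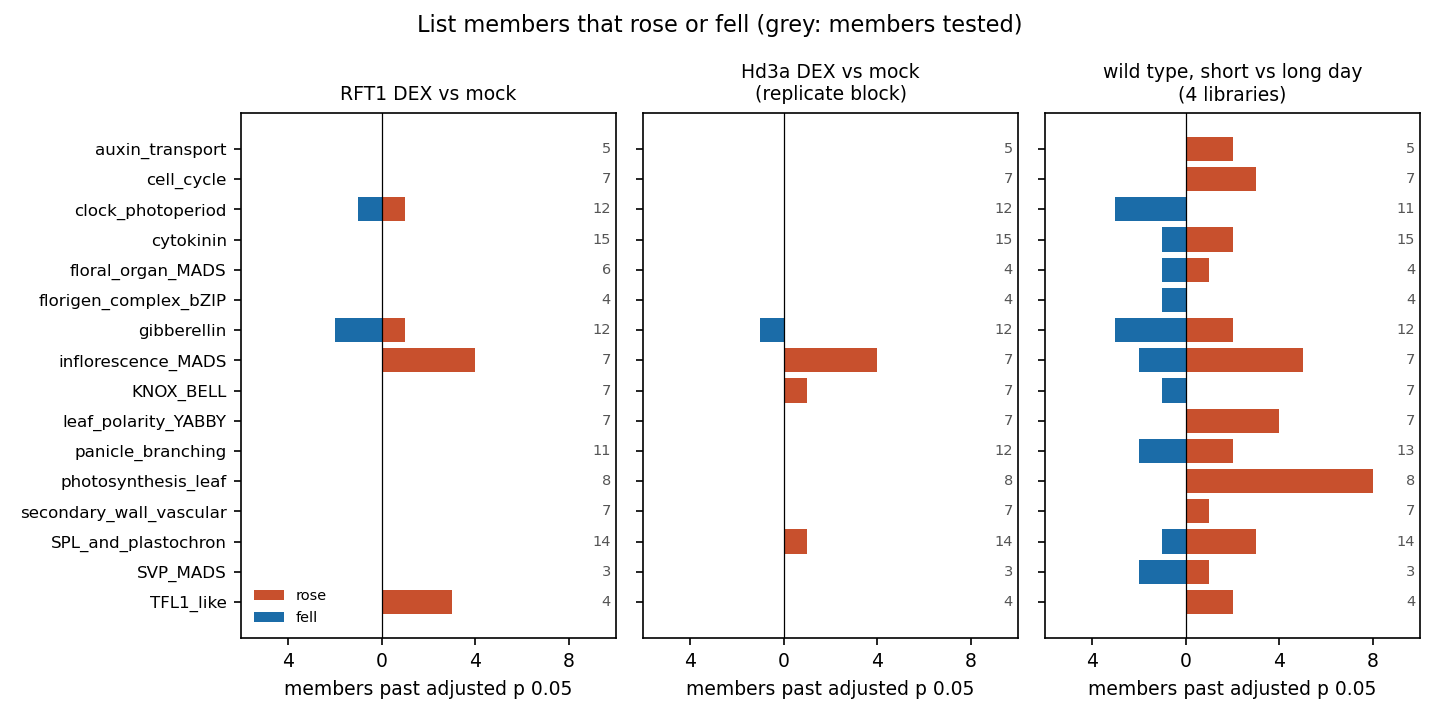
Number of members of each fixed gene list that rose or fell (adjusted p under 0.05 over all genes tested) in RFT1, in Hd3a with the replicate block and in wild type over the 4 libraries with matching labels. Grey numbers give the members tested; 8 of 8 photosynthesis genes rose in wild type and 0 of 8 passed in the other comparisons.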

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

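Written only after the result was seen were all tests of the positions of S15 and S19, those of the Hd3a libraries numbered 1 and of larger spread, and the counts of splits, except the count for RFT1-called genes in Hd3a. That count and the test of effect size were set before their results were seen.

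The gene LOC_Os12g36680 responded more strongly to RFT1 than to Hd3a in the fit with the replicate block, with a difference of 2.86 ± 0.19 (log2, SE, adjusted p = 0.0117) between a rise of 5.33 in RFT1 and 2.47 in Hd3a. Without the block the difference was 2.90 ± 0.81 (adjusted p = 0.56), and DESeq2 gave an adjusted p of 0.138. The check for pairing by replicate number had failed for the RFT1 libraries (-0.21, 0.00 and 0.08). Over the 10 libraries with matching labels the rise was also larger in RFT1 than in short days, by 2.15 ± 0.26 (adjusted p = 0.0399). Between RFT1 and Hd3a, day and transgene differ together, and no further explanation was tested.

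Over genes called in RFT1, both wild-type libraries with conflicting labels lay with the other day length. Positions were put on a scale from 0 (mean of the long-day libraries with matching labels) to 1 (mean of the short-day ones). Over 70 genes called in RFT1 that differed by at least 1 log2 unit between these libraries, the median position was 0.938 for S15 and -0.0119 for S19. Exchanged titles are thus a candidate explanation that these genes leave open. Mixed material would place both between the groups. For these 70 genes, positions of 0.913 and -0.00258 on the CPM scale argue against it. Over all 780 genes called with at least 1 log2 unit, the CPM positions were 0.867 in S15 and 0.143 in S19. Plants of S15 may also have been induced in long days, and plants of S19 not induced in short days. These positions cannot tell that apart from exchanged titles. The 3 clock genes that changed (PRR73, GI and ELF3-2) had median positions of 1.17 in S15 and 0.145 in S19, and 3 are too few. PRR73 alone lay at 1.73 and -0.912, outside the scale. The photosynthesis genes had median positions of 0.515 in S15 and -0.0659 in S19. On the CPM scale they lay at 0.394 and -0.0545. For these genes S15 thus stood between the groups, and mixing stays open.

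For several lists the Hd3a libraries numbered 1 differed from the others of their group in the same direction in both groups. Panicle branching genes (-0.29 in mock and 0.53 in DEX) and gibberellin genes (0.1 and -0.14) did not share a direction. Photosynthesis genes had a median difference of -2.49 (log2) in mock and -1.62 in DEX, and KNOX and BELL genes one of 0.75 and 0.62, all 7 higher in both. The depths of these libraries, 29.3 and 43.7 in units of 1e+06 counts, were the middle ones of the 3 in their group. This argues against total depth as the cause. Both nevertheless held counts for the fewest genes of their group (28407 in mock and 30142 in DEX). The most abundant gene also took its largest share of the group there (1.05% and 2.87%). What these differences reflect was not tested. Less leaf tissue in both may contribute, but it cannot be told apart from other differences, because 4 of 7 YABBY genes were lower in both and 3 higher. Secondary wall genes were also lower (-1.34 and -1.29) and clock genes higher (0.53 and 0.76), and no biological explanation was tested.

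Fewer genes were called in Hd3a than in RFT1. Larger spread between libraries is a candidate explanation: without both libraries numbered 1 the Hd3a test called 121 genes, against 97, 30 and 73 in RFT1 fits of the same size, while leaving out number 2 or 3 in Hd3a gave 0 and 0. A smaller effect of Hd3a at 5 days is also open. Of 664 genes called in short days with a change of at least 1 log2 unit, 67.6% had a larger fold change, in the direction of short days, in RFT1 (medians 0.25 and -0.04). Leaf markers, day and transgene differ along with it.

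Other splits of the libraries into groups of the same size were too few (10 for 3 against 3, and 4 within pairs) for a share under 0.05. For RFT1, 1 of the 10 splits, the real one, called 264 genes and the highest other 0. For the number of lists passing in RFT1, 3 splits gave 4 or more (highest other 4). For Hd3a without the block all 10 splits gave 0, while with it the real split called 54 genes and the highest of the others 0 (1 of 4). The lists passing in Hd3a numbered 6, reached by 3 splits (highest other 7), and those in wild type 3, reached by 3 splits (highest other 5). For wild type by title the real split called 0 and another 6011, the one that exchanges S15 and S19, which points to a structure of the samples. Of the genes that rose in RFT1, 40 passed over that list in Hd3a, reached by 1 of 10 splits (highest other 0). For the interaction and for genes called in all comparisons the real count was 0, so all 100 of 100 drawn splits reached it by construction (highest other 258 and 0), and the draws say nothing about chance. The count of 258 came from 2 draws that exchanged all DEX and mock labels of Hd3a and kept those of RFT1, so that the term adds the RFT1 and Hd3a responses. The 23 genes called in all comparisons with the block and the 4 wild-type libraries were not put through such draws.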

How the results depend on the processing

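The alternatives were planned, apart from those named in the methods as added after the data were seen. Scaling by DESeq2 size factors left the counts of called genes in the 3 comparisons, in the difference between RFT1 and Hd3a and in all comparisons together within 1.5 times their values, as did library totals and a mean CPM minimum for the 3 comparisons, the only counts they were run for. Among alternatives for named genes, 129 kept the call in RFT1 and 26 lost it, 75 left the gene uncalled in Hd3a and 23 called it, and 693 left it uncalled in wild type by title and 100 called it, with no direction reversed for a called gene. For lists that passed, the call was lost under 11 alternatives in RFT1, 26 in Hd3a and 7 in wild type. The cause was not tested for the changes below, except that fewer libraries, or exchanged ones, enter by construction.

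With no filter on low counts the calls were 506 in RFT1, 6 in Hd3a and 1 in wild type. The DESeq2 Wald test called 1274, 171 and 7 genes, and 81 for the difference between RFT1 and Hd3a. The replicate block gave 132 in RFT1, 54 in Hd3a and 1 for the difference. Hd3a without both libraries numbered 1 gave 121. Wild type gave 6011 with S15 as short day and S19 as long day, and 4513 without both. Genes called in all 3 comparisons numbered 23 with the block and without S15 and S19, and 22 with the block and both exchanged.

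The correlation of fold changes between RFT1 and Hd3a was 0.13 with no filter and 0.29 in the joint fit. Between RFT1 and wild type it was 0.02 with no filter, 0.38 with S15 and S19 exchanged and 0.32 without them, with or without the block. Between Hd3a and wild type it was 0.08 with the exchange and 0.05 without both, and with the block 0.09 and 0.05. With an estimated correlation the number of lists passing was 0 in RFT1, 0 in Hd3a and 0 in wild type. With fry, tested for a shared direction, inflorescence MADS passed in RFT1 (adjusted p = 5.02e-05). TERMINAL FLOWER 1-like (0.0577), clock (0.0781) and photosynthesis (0.717) genes did not. No list passed fry in Hd3a with the block (lowest adjusted p = 0.0503). In the 4 wild-type libraries photosynthesis passed fry (0.0217) and YABBY did not (0.0632), and more lists passed with S15 and S19 exchanged. The KNOX and BELL list in wild type turned from lower to higher with S15 and S19 exchanged (adjusted p = 0.664).

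Leaving out a library in turn gave 59 to 168 genes in RFT1 (59 without DEX replicate 2, 87 without DEX replicate 3, 112 without mock replicate 3, 138 without DEX replicate 1, 152 without mock replicate 2, 66 of them higher and 86 lower, and 168 without mock replicate 1), 0 to 5 in Hd3a (5 without mock replicate 1), 0 to 0 in wild type, 0 to 1 for the difference (1 without Hd3a mock replicate 1) and 0 to 0 for genes called in all comparisons. Correlations ran from 0.31 to 0.46 for RFT1 and Hd3a, from -0.07 (without long day replicate 3) to 0.26 (without long day replicate 2, S15) for RFT1 and wild type, and from -0.08 to 0.09 for Hd3a and wild type. Lists passing numbered 2 to 4 in RFT1, 0 to 8 in Hd3a and 2 to 3 in wild type. The read ratio of RFT1 ran from 3.76 (without DEX replicate 3, where its counting interval includes 1) to 27.7 (without mock replicate 1), with 7.98 without mock replicate 3. That of Hd3a ran from 2.72 (without mock replicate 2) to 5.06, with no value without mock replicate 3, since mock then held 0 reads. Reads of RFT1 and Hd3a were too few for a fold change in most libraries, and the reason was not tested.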

Other observations

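The comparison of RFT1 with short days was chosen after the data were seen.

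Over the 10 libraries whose labels match, 20 of 25009 genes differed between the RFT1 and the short-day response in edgeR (12 with the higher value in RFT1, 8 with the lower). OsMADS20, a FRUITFULL-like MADS-box gene, was 1 of them: it fell by 5.21 in short days and gave -0.91 ± 0.21 after RFT1 induction (adjusted p = 0.0931), a difference of 4.31 ± 0.46 (log2, SE, adjusted p = 0.0165). CKX2 differed by 1.66 (adjusted p = 0.1) and psaD by -1.41 (adjusted p = 0.0932), neither past the threshold. Genotype, treatment and time label differ along with this comparison.

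The first principal component of all 18 libraries, with 52.1% of the variance, separated wild-type from transgenic libraries, which also differ in spraying, time label and library series, so genotype cannot be separated from these. The second held 12.3%.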
